A study of Mus musculus with 12 samples.

How the data were processed

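ATAC-seq, which cuts open chromatin with a transposase and counts the resulting fragments by position, was applied to 12 samples of mouse T helper cells in 4 groups of 3. Per the labels' protocols, naive CD4+ T cells from spleen and draining lymph nodes were differentiated in culture towards the homeostatic Th17 state, with or without the synthetic glucocorticoid dexamethasone (Dex) for 2 days, and 6000 sorted cells went into each library, which was amplified for 16 PCR cycles. The cells were wild type (WT) or carried a conditional knockout (cKO) of the glucocorticoid receptor, which the gene Nr3c1 encodes. Each sample was assigned to its group from its own labels.

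The values analysed were deposited by the authors as raw whole-number counts per peak for a joint set of 222105 peaks, with no normalisation per the file headers. Per the submitters' processing notes, the tools were Trimmomatic 0.39, Bowtie2 2.3.5, Picard 2.18.27, SAMtools 1.3, deepTools 3.5.6, Genrich 0.6.1 and featureCounts 2.1.1, and the genome build was mm10. The role of each tool, the filters, any shift of reads for the transposase cut, whether reads or fragments were counted, and whether peaks were called on pooled samples are not given in the sources used here. Peaks called jointly on samples that include the Dex-treated ones can favour sites open in those samples. PCR copies without molecular identifiers are not independent molecules, and nothing in the labels says that the 3 samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples. Count totals ran from 12988437 to 25081591 per library. Replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom between 2.04 and 3.72, so none was treated as a duplicate.

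Peaks were filtered with filterByExpr in edgeR 4.0.16 under R 4.3.3 (minimum count 10, minimum total count 15), which kept 202587 peaks and left out 19518. Counts were scaled by TMM, and edgeR's robust quasi-likelihood F-test was fitted to all 12 libraries with 1 coefficient per group, leaving 8 residual degrees of freedom. The contrasts were Dex in WT, Dex in cKO, the difference between those Dex effects (the interaction), genotype in control cells and genotype in Dex-treated cells. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested peaks, and peaks with an adjusted p under 0.05 are referred to as called. The standard error (SE) of a log2 fold change was its size divided by the square root of F. CPM values are normalised read counts from the cpm function of edgeR, each count divided by the TMM-scaled size of its library. The median biological coefficient of variation was 25.0%.

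The steps were tested on 10 simulated data sets drawn from the real means and library sizes, each with 200 peaks changed by Dex in WT. Over 202587 peaks per simulation, the Dex contrast in WT called 10.8% of peaks simulated at 1.5-fold, 31.2% at 2-fold, 50.8% at 3-fold and 69.2% at 4-fold. Of 886 calls in all, 64 (7.22%) fell on unchanged peaks, and the share was above 5% in 7 of the 10 simulations, so the threshold ran somewhat liberal. Apart from the planted changes, simulated libraries differed only in size, scaling and random spread, and not in how far counts gather in strong peaks. The share of false calls in the real data can therefore differ. With no true change, 9 peaks in all were called for Dex in cKO and 8 for genotype in control cells. A shifted gene list was called in 10 of 10 simulations.

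A gene table of assembly GRCm38.p6, the same build as mm10, gave the spans of 21896 protein-coding genes without strand, transcript starts, exons or sequence. The rule fixed before the data were examined named the nearest transcript start within 50 kb. It was replaced by the gene whose span holds the peak centre, or otherwise the nearest span within 50 kb, which gave 198823 peaks a gene. Positions are therefore stated only as within a gene or between genes, and the motif analysis and the correction for GC content and width were not run. A gene assigned by position need not be the gene that a peak regulates.

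Gene lists, written before the data were examined from general knowledge, held 354 genes, of which 346 had a peak. The 23 lists were glucocorticoid receptor (GR) target genes, non-pathogenic Th17, pathogenic Th17, Th17 core, Th1, Th2, Treg, Tfh, naive and memory T cell, activation and AP-1, NF-kB and inflammatory, co-inhibitory receptor, steroid synthesis and sensing, circadian clock, apoptosis, chemokine receptor and trafficking, TGF-b and STAT signalling, lipid and glucose metabolism, B cell, CD8 T and NK cell, myeloid and dendritic, erythroid and stromal, and ubiquitous promoter genes. A gene counted as higher or lower when it had a called peak in that direction. Lists were tested with camera (limma 3.58.1) on voom values of all their peaks with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 23 lists. Camera with an estimated correlation and fry stood beside it. A camera test asks whether a list's peaks shift against all other peaks, and fry whether they move on balance in 1 direction.

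The rule for named peaks was also fixed in advance. In each comparison it took the 8 higher and 8 lower called peaks with the smallest p whose groups did not overlap, 1 per gene at most. It added up to 3 genes per list by the smallest p, called peaks first, and a fixed set that included Nr3c1, Fkbp5, Tsc22d3, Per1, Zbtb16, Il10, Maf, Il17a, Il17f, Il23r, Csf2 and Cyp11a1. Other peaks that are named were chosen after their values were seen, and the text says so.

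Alternatives covered the scaling (DESeq2 size factors, total counts, loess offsets and quantile normalisation with limma), the count filter, the test (DESeq2 1.42.0, limma-voom, and voom with sample quality weights), the samples in the fit, the replicate number as a block, stricter thresholds, autosomes only, the set test, the distance to genes and the removal of each library in turn. Correlations across peaks used log2 CPM with a prior count of 2 and carry no p, since peaks are not independent replicates. Relations between comparisons that share the WT control libraries were set beside values simulated for unchanged groups. Correlations across libraries used 100000 random permutations. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.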

Results

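Chromatin accessibility was measured in mouse CD4+ T cells cultured towards the homeostatic Th17 state, a form of the IL-17-producing helper T cell associated with barrier tissue and low inflammatory potential. The 12 libraries formed a 2 by 2 design of genotype and treatment with n = 3 per group. WT cells and cells with a conditional knockout of the glucocorticoid receptor (cKO) were cultured without Dex (control) or with Dex, a synthetic agonist of that receptor. Total counts over the 222105 peaks were 12988437, 21138353 and 24595233 in the WT control libraries and 17229355, 19384292 and 17537922 in the WT Dex libraries. They were 15620547, 19133536 and 14796049 in the cKO control libraries and 25081591, 24065321 and 17828441 in the cKO Dex libraries.

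The libraries also differed in how far counts were concentrated in the strongest peaks. The 10% of tested peaks with the highest mean level held 61.2% ± 0.772 of counts in WT control, 62.6% ± 1.52 in WT Dex, 58.9% ± 1.27 in cKO control and 60.3% ± 1.88 in cKO Dex (SD, n = 3). Over the 12 libraries this share followed the first principal component, which held 20.7% of the variance, with Pearson's r = 0.852 (permutation p = 0.00031, two-sided) and Spearman's rho = 0.867 (permutation p = 0.00061). Pearson's r was 0.772 without the 2 libraries farthest from the median share. The labels name no batch, so no within-batch value can be given.

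Nr3c1, the gene targeted in the cKO, was compared between genotypes at its 24 tested peaks. Its strongest peak, within the gene on chromosome 18 from 39488851 to 39492392 (mm10), stood at 60.2, 74.4 and 70.1 CPM in the WT control libraries and at 74.9, 82.0 and 65.3 CPM in the WT Dex libraries. It stood at 52.3, 60.6 and 57.4 CPM in the cKO control libraries and at 69.9, 61.5 and 57.1 CPM in the cKO Dex libraries. The log2 fold change, cKO over WT, was -0.27 ± 0.10 (SE, n = 3 per group) in control cells with an edgeR adjusted p of 0.532. No Nr3c1 peak was called, and the smallest adjusted p was 0.501 in control and 0.380 in Dex-treated cells; 4 and 3 of the 24 peaks had an unadjusted p under 0.05. Accessibility reports open chromatin and not transcript or protein, and the position of the deleted part is not given in the sources used here, so these values do not check the genotype labels.

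Dex treatment of WT cells asked where receptor activation changes chromatin. The call with the smallest p lay on chromosome 2 from 155051715 to 155053366, 1528 bases outside nonagouti, which encodes a secreted antagonist of melanocortin receptors. Accessibility there rose 9.09-fold (log2 3.18 ± 0.15, SE, n = 3 per group). A peak between genes near Cxcr4, the chemokine receptor that retains lymphocytes in bone marrow (chromosome 1, 128614316 to 128615908), rose from 15.2 ± 1.12 to 59.1 ± 1.54 CPM (SD, n = 3), or 3.86-fold. A peak near Klf9, a transcription factor gene induced by glucocorticoids in many cell types, rose from 32.7 ± 0.921 to 76.3 ± 9.72 CPM, and a peak near Il7r, the receptor chain for the survival cytokine IL-7, rose 2.66-fold. In the other direction, a peak near Bhlhe40, a transcription factor needed for inflammatory cytokine output of helper T cells, fell by 0.83 ± 0.15 on the log2 scale, and a peak within Il23r, the receptor that drives pathogenic Th17 cells, fell by 0.73 ± 0.15. The call at Il23r was lost without WT control replicate 3, at a log2 of -0.68.

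Of 202587 tested peaks, edgeR called 1081, with 851 higher and 230 lower after Dex. The count was 719, 635 and 603 without WT control replicates 1, 2 and 3, and 507 and 624 without WT Dex replicates 1 and 2. The 1081 peaks were assigned to 718 genes, and 383 of them changed at least 2-fold, 315 higher and 68 lower. Called peaks lay within a gene in 52.5% of cases, against 58.3% of all tested peaks. The other leading higher peaks were near Cradd, an adaptor of cell death signalling (log2 2.81 ± 0.19), near Khdc1a (2.76 ± 0.21), near Grxcr2 (1.87 ± 0.14), within Ppp1r21 (1.84 ± 0.12), near Mchr1 (1.70 ± 0.12), and on chromosome 6 from 31345099 to 31346034, over 50 kb from any protein-coding gene (2.91 ± 0.16). The other leading lower peaks were near Hilpda, a hypoxia-induced regulator of lipid droplets (log2 -1.23 ± 0.22), within Sorcs2 (-1.22 ± 0.20), near Car12 (-1.06 ± 0.19), near Cysltr2, a leukotriene receptor (-0.97 ± 0.17), within Kat6b (-0.93 ± 0.17), within Capzb (-0.80 ± 0.14) and near Cnot4 (-0.74 ± 0.13). The share of higher calls was 78.7% and moved with the scaling: 58.7% of 1757 calls with total counts, 58.9% of 2120 with loess offsets, 60.02% of 1781 with quantile normalisation, and 47.9% of 2243 with the concentration share as a covariate, an alternative added after seeing the data.

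**Figure D1:**
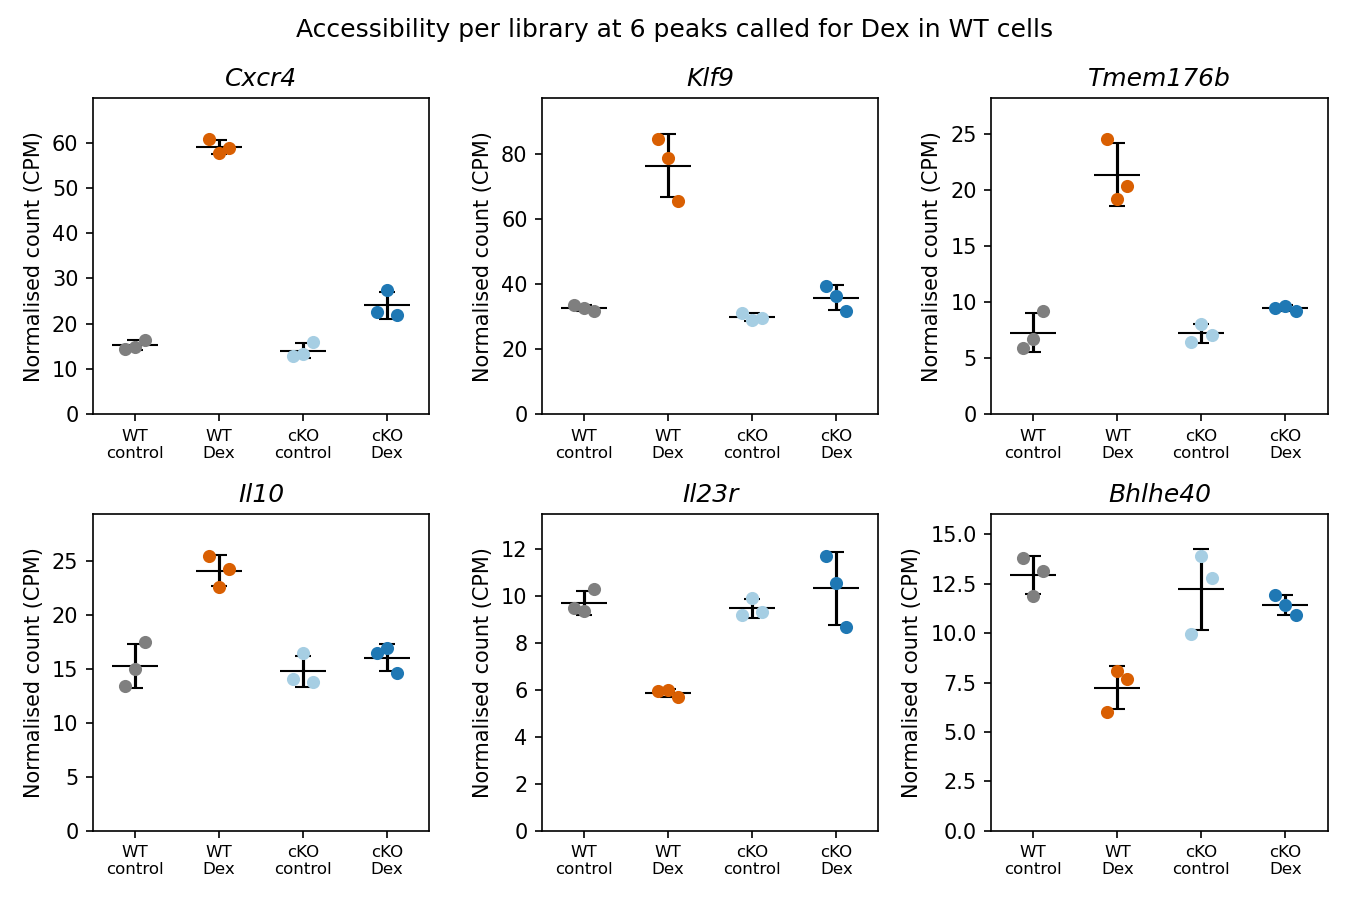
Normalised counts (CPM, vertical axes) at peaks assigned to 6 genes, by group (horizontal axes); points are libraries, the long bar is the mean and the whiskers are 1 SD (n = 3). The peaks near Cxcr4, Klf9 and Tmem176b and within Il10 were higher with Dex in WT cells, at 59.1, 76.3, 21.4 and 24.1 CPM on average, and those within Il23r and near Bhlhe40 were lower, at 5.86 and 7.24 CPM.

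Of 30 GR target genes, 10 had a higher peak, none had a lower one, and 20 had no called peak. The list passed camera with an adjusted p of 0.00889, and fry gave 0.0232, but the call was lost with an estimated correlation (adjusted p = 0.0625). It was also lost with loess offsets, with the concentration share as a covariate and without WT control replicate 3, each leaving 0 lists. Adjusted over the list alone, 13 genes had a higher peak and 1 a lower one. Beside Cxcr4, Klf9 and Il7r, the higher genes were Txnip, Sgk1, Zfp36l2, Dusp1, Il1r2, Zbtb16 (log2 1.60 ± 0.25) and Tsc22d3 (0.92 ± 0.19), of which Tsc22d3 encodes the anti-inflammatory protein GILZ and lost its call without WT control replicate 1 (0.74). No peak of Fkbp5 or Per1, classical receptor targets, was called. Their peaks with the smallest p in this comparison had log2 values of 1.76 ± 0.67 and 0.09 ± 0.09.

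Single genes of the Th17 programme changed, while none of their 3 lists shifted in 1 direction by camera. In the non-pathogenic Th17 list, 2 of 12 genes had a higher peak and none a lower one: Il10, an anti-inflammatory cytokine, rose from 15.3 ± 2.05 to 24.1 ± 1.47 CPM, and Cd5l, a restrainer of Th17 pathogenicity, had a log2 of 0.97 ± 0.24 that lost its call without any of 5 of the 6 WT libraries. In the pathogenic Th17 list, 3 of 20 genes had a higher peak (Icos, Lag3 and Il1r1) and 2 a lower one (Bhlhe40 and Il23r). In the Th17 core list, 5 of 18 had a higher peak, among them Tmem176b (log2 1.53 ± 0.15), Hif1a, a hypoxia response factor that favours Th17 cells (1.08 ± 0.14), and Il21 (0.70 ± 0.15), besides Il1r1 and Sox5. Adjusted over the list alone, the counts were 2 higher and 0 lower, 3 higher and 2 lower, and 6 higher and 1 lower, and the camera adjusted p was 0.649, 0.917 and 0.917. Fry for changes in either direction gave adjusted p of 0.0408, 0.000274 and 0.00869 for these lists, and 0.0308 for the ubiquitous promoter genes, none of which was called. The peaks of Il17a, Il17f, Maf and Csf2 with the smallest p were not called, at log2 values of -0.91 ± 0.52, 1.65 ± 0.62, 0.52 ± 0.17 and 1.04 ± 0.38.

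Among genes of other T cell states, 3 of 14 naive and memory genes had a higher peak. These were Il7r, Foxp1 (log2 0.72 ± 0.11) and S1pr1, the receptor for lymphocyte egress (0.82 ± 0.14). The naive and memory genes carried 818 tested peaks, of which 4 were called higher, a similar share to the 851 of 202587 over all peaks. Of the 13 co-inhibitory receptor genes, 3 had a higher peak, led by Prdm1, which encodes the regulator Blimp-1 (1.72 ± 0.29), with Lag3 and Ctla4. Single higher genes were Il12rb2 of 14 Th1 genes, Ctla4 of 13 Treg genes and Tox of 10 Tfh genes, and none of 11 Th2 genes had a called peak. Adjusted over the list alone, the counts were the same except for 1 lower co-inhibitory gene. The camera adjusted p was 0.0643 for the co-inhibitory list (0.377 with an estimated correlation) and at least 0.301 for the Th1, Th2, Treg, Tfh and naive and memory lists.

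Apoptosis genes included both directions: 3 of 14 had a higher peak, namely Bcl2l11, which encodes the death promoter Bim (log2 1.24 ± 0.14), its antagonist Bcl2 (0.55 ± 0.10) and Pmaip1, and Fas had a lower one. The circadian clock list held 1 higher gene, Npas2 (1.46 ± 0.17), and 1 lower, Bhlhe40, of 14. The activation and AP-1 list had 2 higher genes (Cd69 and Batf3) and 2 lower (Fosl2 and Jun) of 21, and the NF-kB list had 1 higher, Nfkbiz (1.10 ± 0.18), of 18. Lipid and glucose metabolism had Ppard higher (0.96 ± 0.17) and Pparg lower of 21, chemokine receptors had P2ry10 higher of 13, and TGF-b and STAT signalling had Jak1 higher of 16. No gene was called among 20 of steroid synthesis and sensing or 20 ubiquitous promoters. Adjusted over the list alone, the counts differed for apoptosis (4 higher), the clock (2 lower), NF-kB (2 higher), chemokine receptors (3 higher) and TGF-b and STAT (0). The camera adjusted p was 0.231 or more for all 9 lists.

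Markers of other cell types were tested in the same way. Of 10 B cell genes, 1 had a lower peak, Ebf1 (log2 -0.49 ± 0.13), in the count over all peaks and in that adjusted over the list alone. The camera adjusted p of this list was 0.0643 and fry gave 0.0275, both downwards. No gene was called among 10 CD8 T and NK cell, 14 myeloid and dendritic or 10 erythroid and stromal genes, whose camera adjusted p was at least 0.647; adjusted over the list alone, 1 CD8 T and NK cell gene was lower.

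Dex in cKO cells asked what remains without the receptor. The peak near Cxcr4 rose from 14.05 ± 1.66 to 24.1 ± 2.99 CPM (SD, n = 3), which is 1.72-fold against 3.86-fold in WT. The nonagouti peak rose 1.83-fold, the chromosome 6 peak from 31345099 rose 2.13-fold and the Khdc1a peak 2.99-fold. A peak within Neb, the gene of the muscle protein nebulin (chromosome 2, 52304449 to 52305279), and a peak on chromosome 2 from 149283289 to 149283661, far from any protein-coding gene, rose by log2 values of 1.48 ± 0.27 and 1.81 ± 0.31. These 6 were all the calls of edgeR, 6 higher and 0 lower, and all 6 were also called in WT. An unadjusted p under 0.05 was reached by 11840 peaks (5.84%), where no change at all would give a share near 0.05. Cxcr4 was the only called gene of any list, at 1 of 30 GR target genes, also when adjusted over the list alone, and the camera adjusted p was at least 0.338 for all 23 lists. The count was 10 with DESeq2, 2 with limma-voom, 3 with the cKO libraries alone and 58 with sample quality weights, of which 50 were lower. Without cKO Dex replicate 3 it was 314, of which 273 were lower, and it was 1, 3, 2 and 2 without cKO control replicate 1, 2 or 3 and cKO Dex replicate 2.

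Whether the Dex effect differed between genotypes was tested directly by the interaction. The Dex effect was larger in WT than in cKO at nonagouti by a log2 of 2.31 ± 0.21, at Cxcr4 by 1.17 ± 0.16, at Klf9 by 0.96 ± 0.15 and at Tmem176b by 1.14 ± 0.21 (SE, n = 3 per group). A peak within Cab39l differed by 3.49 ± 0.46, with 0.780 CPM in WT control and 8.56 CPM in WT Dex against 1.21 and 1.28 CPM in cKO. EdgeR called 56 peaks, 55 with the larger signed log2 value in WT and 1 with the larger signed value in cKO. Of the 56, 54 were also called for Dex in WT. That comparison shares the 6 WT libraries with the interaction, so the overlap is not independent. Of the list genes, 3 of 30 GR targets (Cxcr4, Klf9 and Sgk1), 2 of 18 Th17 core genes (Tmem176b and Hif1a), Nfkbiz and Bcl2l11 had a called peak. The Sgk1 peak was weak, at 0.805 CPM in WT control and 2.57 CPM in WT Dex. In cKO it stood at 2.27 CPM in control and 1.56 CPM with Dex, so part of its difference is a lower value with Dex in cKO. Adjusted over the list alone, there were 6 GR targets, in the Th17 core 2 larger and 1 smaller in WT, and 1 larger in each of the NF-kB, apoptosis, naive and memory, co-inhibitory and circadian clock lists. No list passed, with a smallest camera adjusted p of 0.822.

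**Figure D2:**
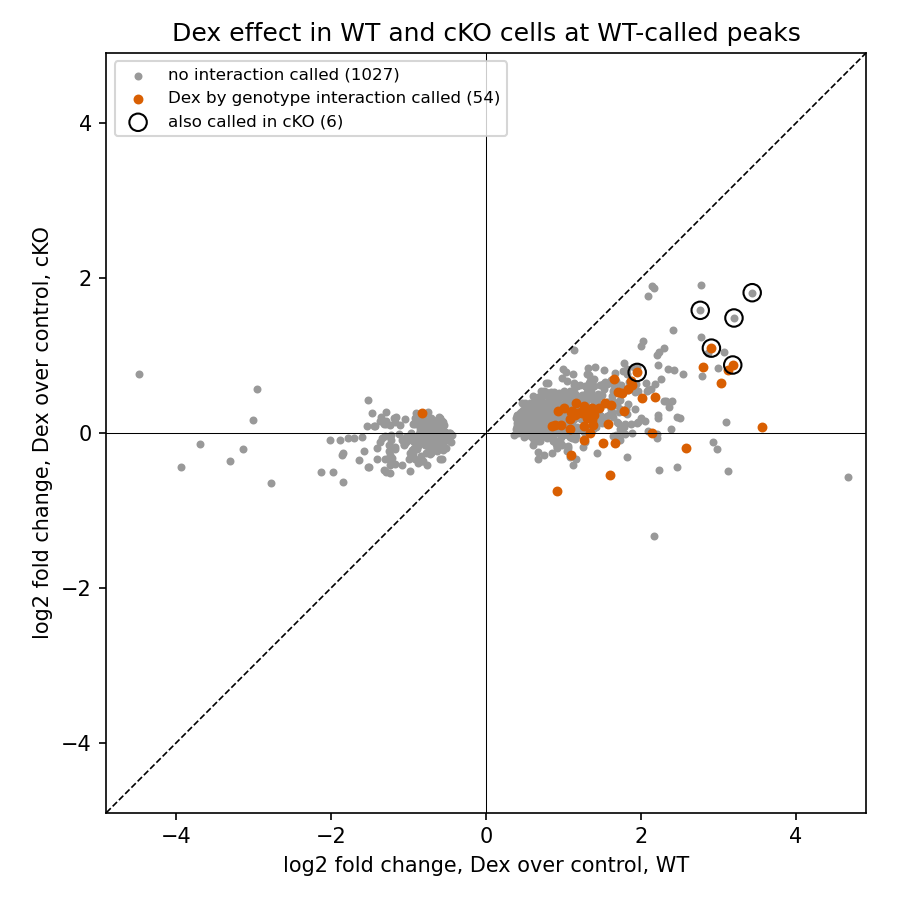
Log2 fold change of Dex over control in WT cells (horizontal axis) against that in cKO cells (vertical axis) for the 1081 peaks called in WT; the dashed line marks equal effects. Of these, 54 were also called for the interaction and 6 for Dex in cKO, and the peaks higher in WT had a median log2 of 0.83 in WT and 0.21 in cKO.

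The interaction count rose to 113 with total counts, 190 with loess offsets, 129 with quantile normalisation and 114 with sample quality weights. With the concentration share as a covariate it was 246, of which 84.6% were larger in WT against 98.2% of the 56. Among the 851 peaks higher with Dex in WT, 765 (89.9%) also had a positive log2 in cKO, against 49.5% of all tested peaks, with a median of 0.21 in cKO and 0.83 in WT. Among the 230 lower peaks, 153 (66.5%) were negative in cKO, with a median of -0.06 against -0.81. These peaks were selected on the WT libraries, which makes the WT medians larger in size. The cKO log2 values were not used in that selection. However, the mean concentration share was higher with Dex in both genotypes, so peaks that follow it can agree in sign. With that share in the fit, 81.2% of the peaks higher with Dex in WT were positive in cKO. Across all tested peaks the correlation of the 2 Dex effects, which share no library, was r = 0.0651, against 0.00112 in simulated unchanged groups, and it turned to -0.0368 without WT control replicate 1. The simulated libraries did not differ in concentration share beyond random spread, so 0.00112 is not a full reference. Over the called peaks r was 0.575; these are correlations across peaks, which are not independent replicates.

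Genotype in control cells asked whether receptor loss changes chromatin without added Dex. A peak within Rhoh, a GTPase gene required for T cell receptor signalling (chromosome 5, 65862850 to 65863924), stood at 19.9 ± 1.97 CPM in WT control and 8.25 ± 1.03 CPM in cKO control (SD, n = 3), a log2 of -1.27 ± 0.14. A peak near Chrna9, an acetylcholine receptor subunit gene (chromosome 5, 65991020 to 65991658), stood at 20.6 ± 1.25 and 9.65 ± 0.946 CPM. Both lie in an interval of 160 kb on chromosome 5, from 65844768 to 66004802, in which 57 tested peaks in a row were lower in cKO on average over both treatments, with a median log2 of -0.90. The interval was singled out after its values were seen. The 150 peaks within 400 kb on either side had a median of 0.06. Summed over the interval, WT libraries held between 341 and 367 CPM and cKO libraries between 166 and 200 CPM, a ratio of 0.512. The next longest run of lower peaks in the genome held 22.

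EdgeR called 21 peaks for genotype in control cells, 2 higher and 19 lower in cKO, and 17 of the 21 lay in this interval. The 4 outside it were within Mad1l1 (log2 1.79 ± 0.35) and Atp2a2 (2.24 ± 0.45), both under 3 CPM in every group mean, within Snd1 (-0.79 ± 0.15) and near Ctnnbip1 (-0.60 ± 0.12). No gene of the 23 lists had a called peak; adjusted over the list alone, 1 GR target gene and 1 apoptosis gene were higher. No list passed, with a smallest camera adjusted p of 0.611. Without the interval, an alternative added after seeing the data, edgeR called 0 peaks, so that Mad1l1, Atp2a2, Snd1 and Ctnnbip1 were lost. Of all tested peaks, 15579 (7.69%) had an unadjusted p under 0.05, where no change at all would give a share near 0.05. The count was 371 with DESeq2, of which 370 were lower, 254 with sample quality weights, 96 with the control libraries alone, 75 with quantile normalisation, 48 with loess offsets and 38 with total counts. It was 13 without cKO control replicate 2 and 54 without cKO Dex replicate 3. The share higher was 9.52%, from 0% to 18.5% with 1 library left out, against 48.0% with quantile normalisation, 43.8% with loess offsets, 23.7% with total counts and 21.1% with the concentration share as a covariate.

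**Figure D3:**
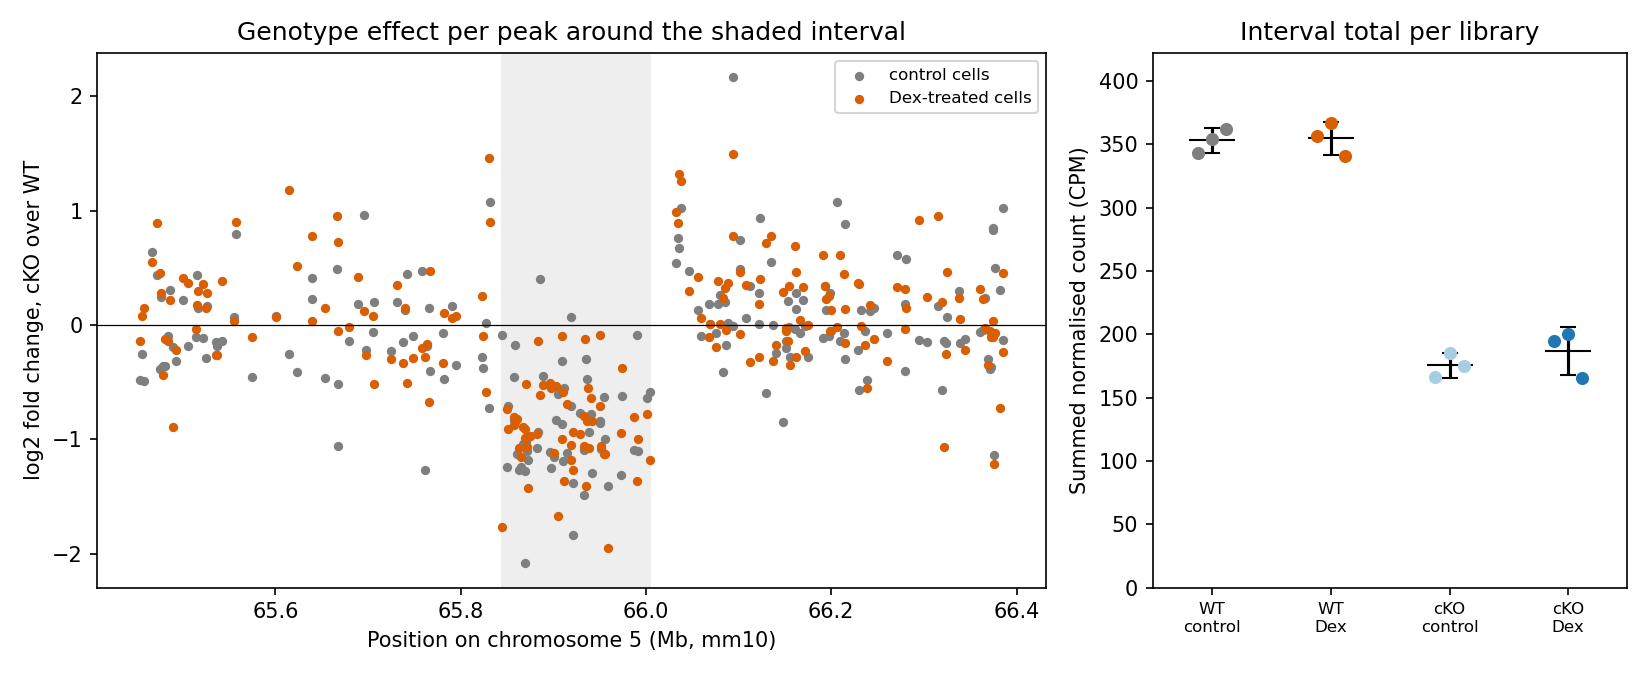
Left, log2 fold change of cKO over WT for each tested peak (vertical axis) by position on chromosome 5 in Mb (horizontal axis, mm10), in control and Dex-treated cells, with the interval shaded. Right, summed normalised counts (CPM) over the interval by library, with the mean and 1 SD (n = 3); group means were 353 and 355 CPM in WT and 175 and 187 CPM in cKO.

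Genotype in Dex-treated cells compared the genotypes once the receptor was engaged. In cKO relative to WT, the nonagouti peak was at a log2 of -2.14 ± 0.13, Cxcr4 at -1.30 ± 0.11, Klf9 at -1.09 ± 0.10, Il7r at -0.94 ± 0.14 and Tmem176b at -1.17 ± 0.14 (SE, n = 3 per group). Higher in cKO were a peak near Hilpda (1.32 ± 0.22), a peak near Pmaip1, a death-promoting gene of the Bcl2 family (1.21 ± 0.21), a peak near Car12 (1.06 ± 0.19), and the Il23r peak (10.3 ± 1.54 against 5.86 ± 0.162 CPM), whose call was lost without cKO Dex replicate 1 at a log2 of 0.72. The Il10 peak was lower in cKO, at 16.0 ± 1.24 against 24.1 ± 1.47 CPM, and lost its call without WT Dex replicate 1 (-0.55), cKO Dex replicate 1 (-0.60) or cKO Dex replicate 3 (-0.51).

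EdgeR called 345 peaks, 81 higher and 264 lower in cKO. Of the peaks lower in cKO, 213 were among those higher with Dex in WT, where independent lists would share 1.11, and of those higher in cKO, 33 were among those lower with Dex in WT, against 0.092. These comparisons share the WT Dex libraries, and in simulated unchanged groups that share them equally many of the largest effects overlapped in 28.9 and 23.6 peaks on average. The simulated effects were ranked by log2 size and not by p, unlike the called peaks, so these values are only a rough reference. Of 30 GR target genes, 7 were lower (Cxcr4, Klf9, Txnip, Il7r, Zfp36l2, Zbtb16 and Tsc22d3) and 1 was higher, Fkbp5 (0.54 ± 0.12). That value is from the Fkbp5 peak with the smallest p in this comparison, which need not be the peak given for Dex in WT. Adjusted over the list alone, 11 were lower and 2 higher, and the camera adjusted p was 0.128. In the Th17 core list, 3 of 18 were lower (Tmem176b, Hif1a and Il1r1), or 3 lower and 1 higher adjusted over the list alone, and in the pathogenic list 2 of 20 were higher (Il23r and Bhlhe40) and 1 lower. Further lower genes were Foxp1 and S1pr1 of the memory list, Prdm1 (-1.44 ± 0.28), Npas2, Nfkbiz, Bcl2l11 and Bcl2, and Pparg, like Pmaip1 and Bhlhe40 of the apoptosis and clock lists, was higher. Adjusted over the list alone, the counts of higher and lower genes were 1 and 1 for non-pathogenic Th17, 1 and 4 for naive and memory, 1 and 3 for activation and AP-1, 2 and 2 for the clock, and 1 and 3 for metabolism. They were 1 and 0 for myeloid and dendritic and 2 and 0 for erythroid and stromal genes, and for the lists not named here they did not differ from those over all peaks. No list passed by camera. The share higher was 23.5%, against 56.4% of 894 calls with total counts, 53.5% of 994 with loess offsets, 55.8% of 679 with quantile normalisation and 67.9% of 1784 with the concentration share as a covariate, so which direction held most calls depended on the scaling. Leaving out WT Dex replicate 1, WT Dex replicate 2 or cKO Dex replicate 1 gave 152, 204 and 195 calls. The share higher was 45.1% without cKO Dex replicate 3, and 12.8%, 10.7% and 14.3% without cKO Dex replicates 1 and 2 and WT Dex replicate 3.

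Whether receptor loss in control cells opposes the Dex effect was examined over all tested peaks. Of the 1081 peaks called for Dex in WT, none was called for genotype in control cells, where the 21 calls are too few to show an overlap or its absence. The log2 effects of Dex in WT and of genotype in control cells correlated at r = 0.386 across peaks, and both use the WT control libraries. Their covariance was 0.0656, against 0.0701 in simulated unchanged groups that share those libraries (0.0696 to 0.0707), a difference of -0.00446. The simulations drew peaks independently and gave libraries no differences beyond size, scaling and random spread. Their range is therefore too narrow to judge this difference, and no opposing effect can be read from it. The median log2 of genotype in control cells was 0.10 at the peaks higher with Dex in WT and -0.18 at the lower ones, the same signs as the Dex effect, which the shared libraries favour. With the concentration share as a covariate r was 0.157. The 13 peaks called for genotype in the same direction in control and in Dex-treated cells all lay in the chromosome 5 interval.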

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

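The tests of copy number and of receptor-driven opening of the chromosome 5 interval were chosen only after the results were seen. So were those of carried-over material, and of the concentration share behind a possible residual Dex response and the excess of higher peaks. The concentration share as an explanation of the interval, the retained receptor and the splits of the samples were set down before their results. The allowance for the spread in the test of the retained receptor was not part of its written rule.

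The Dex effect differed between WT and cKO cells, by the interaction test in edgeR, at 56 peaks. The log2 difference, WT minus cKO, was 2.31 at nonagouti, 1.81 at the chromosome 6 peak from 31345099, 1.50 at a chromosome 16 peak from 55582485, 3.49 within Cab39l, 1.27 within Ppp1r21, 1.17 near Cxcr4, 1.95 near Cradd and 1.17 near Mchr1. Among list genes it was 0.96 near Klf9, 1.14 near Tmem176b, 1.03 near Hif1a, 1.38 near Nfkbiz and 0.98 within Bcl2l11. Within Sgk1 it was 2.15, at a weak peak that also stood lower with Dex in cKO. A chromosome 2 peak from 18604170, with no gene within 50 kb, was the single peak with the larger signed value in cKO, at -1.09. It fell with Dex in WT, from 10.8 ± 0.914 to 6.09 ± 0.456 CPM (SD, n = 3). In cKO it stood at 8.33 ± 0.905 CPM in control and 9.87 ± 2.62 CPM with Dex. Of 24 drawn splits of the samples, 4, the real one included, gave at least 56 peaks, and the highest of the others gave 1379, so chance is not excluded for the count. A split that calls many times the real number points to a structure of the samples, and what it follows was not tested. Leaving out WT control replicate 3, WT Dex replicate 1, cKO control replicate 3 or cKO Dex replicate 1 gave 34, 29, 31 and 33 peaks, and leaving out cKO Dex replicate 3 gave 177.

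A chromosome 5 interval from 65844768 to 66004802, which holds peaks within Rhoh and Chrna9 and was picked as the longest run of lower peaks, was lower in all 6 cKO libraries than in all 6 WT libraries, at 0.512 of the WT level. Opening of the interval by the receptor is argued against by its log2 change with Dex in WT of 0.0069 ± 0.038 (SE, n = 3 per group), and the concentration share by a median log2 of -0.84 with that share in the fit, against -0.90 without it. The 28 peaks of the interval with the lower levels, at a median of 0.873 CPM, had a median log2 of -0.87 (SD 0.36), against -0.97 in the others. The near-equal loss at weak and strong peaks is consistent with a difference in copy number between the animals that gave the WT and cKO cells, which is a hypothesis found and tested on the same data. A regulatory effect of the genotype over the whole interval that does not need added Dex stays open and was not tested.

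A residual Dex response in cKO cells rests on the 6 called peaks and on a rise that the libraries do not establish. The summed level of the 851 peaks higher with Dex in WT was 10187 ± 542 CPM in cKO control and 11574 ± 767 CPM in cKO Dex (SD, n = 3). The exact permutation p was 0.2, two-sided, where 0.1 is the smallest the design allows. The rise was 0.216 of that in WT, where the selection of the peaks enlarges the rise. The explanations below concern this rise if it is real. The concentration share as the whole source is argued against. With it in the fit 81.2% of these peaks were still higher in cKO and 5 of the 6 cKO calls were kept. Limits that treat peaks as independent, and so understate the spread, were 78.4% to 83.7%, above the cut-off of that test. Cells that kept the receptor could give such a response in every library. The rule set down beforehand counted any cKO Dex library at or below a cKO control library against this explanation. By that rule the prediction failed, since only 8 of the 9 pairs of a cKO Dex and a cKO control library were ordered that way. The exception, replicate 3 against control replicate 2, lay 14.8 CPM apart against a pooled SD of 664. That allowance was not part of the rule, and with it the libraries are too few to decide. WT Dex material carried over cannot be told apart from cells that kept the receptor either. The interval on chromosome 5 moved by a log2 of 0.087 with Dex in cKO. The limits of that change, -0.18 to 0.36, hold both 0 and the predicted 0.29. The 150 peaks around the interval also stood higher, at 650 ± 26.2 CPM in cKO control and 693 ± 48.0 CPM in cKO Dex (SD, n = 3). The move therefore need not be particular to the interval, and the interval relative to those peaks was not tested. An action of Dex without this receptor also stays open and was not tested.

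More peaks were higher than lower with Dex in WT, at 78.7% of calls. With the concentration share as a covariate 47.9% of the calls were higher, so that a difference between libraries in this share may account for the excess over all calls. Among calls of at least 2-fold, 82.2% were higher in the original fit and 71.3% (392 higher and 158 lower) with the covariate. That percentage lay just above the cut-off set to count against the concentration share. Limits that treat peaks as independent, 67.4% to 74.9%, include the cut-off. Peaks are not independent, so these limits understate the spread, and the concentration share cannot be told apart there. The share is measured on the same counts and was highest in WT Dex, so the covariate can also remove a true effect of Dex on many peaks. Opening by the receptor stays open as the biological explanation.

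For 3 samples against 3 there are 10 splits, too few for a share under 0.05. Dex in WT gave 1081 peaks and the highest other split 0, genotype in control cells 21 and 0, genotype in Dex-treated cells 345 and 26, and Dex in cKO 6 and 244. The split with 244 set cKO control replicates 1 and 3 and cKO Dex replicate 3, the cKO libraries with the lowest concentration shares (57.9%, 58.5% and 58.1%), against the others. For gene lists, Dex in WT gave 1 list and the highest other split 0, and genotype in control cells 0 and 0. The interaction gave 0 lists and the highest other split 1, and since all 24 drawn splits must reach 0 this says nothing about chance. The correlation of the Dex effects in WT and cKO was 0.0651, and 13 of 100 drawn splits gave at least that, up to 0.303; for Dex in WT and genotype in control cells it was 0.386, and 94 of 100 did, up to 0.647. Chance is not excluded for the first of these correlations. For the second, every split keeps a control group shared by both effects, which by itself gives a positive value. The lowest other split gave 0.309, so the count of splits could not exclude chance there.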

How the results depend on the processing

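The fits with the concentration share as a covariate, those without the chromosome 5 interval and the lists limited to peaks within 1 kb of either end of a gene were chosen after seeing the data, and all other alternatives were fixed before the data were examined. All counts below are of peaks called by the named fit, and unless stated otherwise the cause of a difference was not tested.

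Dex in WT gave 1081 peaks, and 1757 with total counts, 2120 with loess offsets, 1781 with quantile normalisation, 1760 with the WT libraries alone and 2243 with the covariate. Of the 1081, 1054, 1079, 1066 and 990 were shared with the total count, loess, quantile and covariate fits. By construction, 571 remained at an adjusted p under 0.01 and 383 at a log2 of at least 1 in size. Dex in cKO gave 6, and 10 with DESeq2, 2 with limma-voom, 58 with sample quality weights, 3 with the cKO libraries alone and 3 at an adjusted p under 0.01. The interaction gave 56, and 113 with total counts, 190 with loess offsets, 129 with quantile normalisation, 114 with sample quality weights, 246 with the covariate and 32 at the stricter p. Genotype in control cells gave 21, and 38 with total counts, 48 with loess offsets, 75 with quantile normalisation, 371 with DESeq2, 254 with sample quality weights, 96 with the control libraries alone and 0 without the interval. Genotype in Dex-treated cells gave 345, and 894 with total counts, 994 with loess offsets, 679 with quantile normalisation, 656 with DESeq2, 737 with sample quality weights, 1784 with the covariate, 194 at the stricter p and 107 at a log2 of at least 1. No scaling moved the median log2 of all peaks by more than 0.1.

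For the lists, Dex in WT gave 1, and 0 with loess offsets, 0 with the covariate, 0 with an estimated correlation, 2 with fry and 3 with peaks near gene ends. Genotype in control cells gave 0 lists, and 3 with the covariate and 4 with peaks near gene ends; the interaction gave 0 in all alternatives run. The correlation of Dex in WT with genotype in control cells, 0.386, was 0.157 with the covariate.

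With the replicate number as a block, Dex in WT gave 1747 peaks, the interaction 99, genotype in control cells 173, genotype in Dex-treated cells 1017 and Dex in cKO 7. Only 3 of 18 same-numbered pairs of libraries deviated together at r above 0.1, so the numbers were not taken to pair the samples, although 8 of 12 libraries correlated best with a library of their own number.

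Leaving out 1 library at a time, Dex in WT ranged from 507 (without WT Dex replicate 1) to 1435 (without cKO Dex replicate 3), with 719, 635 and 603 without WT control replicates 1, 2 and 3 and 624 without WT Dex replicate 2. Dex in cKO ranged from 1 (without cKO control replicate 1) to 314 (without cKO Dex replicate 3), with 3 and 2 without cKO control replicates 2 and 3 and 2 without cKO Dex replicate 2. The interaction ranged from 29 (without WT Dex replicate 1) to 177 (without cKO Dex replicate 3), with 34, 31 and 33 without WT control replicate 3, cKO control replicate 3 and cKO Dex replicate 1. Genotype in control cells ranged from 13 (without cKO control replicate 2) to 54 (without cKO Dex replicate 3) and genotype in Dex-treated cells from 152 (without WT Dex replicate 1) to 454 (without WT Dex replicate 3), with 204 and 195 without WT Dex replicate 2 and cKO Dex replicate 1. Fewer libraries lower the power, but the rises without cKO Dex replicate 3 are not explained by that. That library differed most from its group, with a chi-square per degree of freedom of 3.14 and 3.72 against replicates 1 and 2. These were the highest of all replicate pairs. Its concentration share was 58.1%, against 61.0% and 61.6% in those replicates. Whether this gives the rises was not tested. The lists ranged from 0 (without WT control replicate 3) to 3 (without cKO control replicate 2 or cKO Dex replicate 2) for Dex in WT, with 2 without WT control replicate 2 or WT Dex replicate 3, and stayed at 0 for the others. The correlation of the 2 Dex effects ranged from -0.0368 (without WT control replicate 1), a change of sign, to 0.138, and that of Dex in WT with genotype in control cells from 0.273 to 0.510.

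No called named peak changed sign in any alternative run, and named peaks that were not called were not rerun. The call was kept in 1102 of 1173 values for Dex in WT, 120 of 150 for Dex in cKO, 313 of 360 for the interaction, 105 of 145 for genotype in control cells and 782 of 847 for genotype in Dex-treated cells. It was kept in all alternatives by 30 of 47, 0 of 6, 9 of 15, 2 of 6 and 20 of 34 called named peaks. The GC content, width and motif analyses were not run because no genome sequence was used here, nor was the replicate block with a GC offset or the list of peaks within 1 kb of a transcript start. At this depth, number of replicates and spread, whose parts were not separated, 10.8% of peaks simulated at 1.5-fold were called in WT.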

Other observations

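The tests of peaks that gather at a gene were chosen only after the result was seen, and the peaks of Rbm47 and Pmaip1 were named by the rule fixed before the data were examined.

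Peaks higher with Dex in WT gathered at a few genes. Dthd1, a gene of the death domain family, had 10 higher peaks of 26 tested, Bcas3 had 8 of 92, Dock10, a guanine nucleotide exchange factor of lymphocytes, 8 of 77, and Tnr, the gene of the matrix protein tenascin-R, 7 of 59. Cradd, Fam107b, Mfhas1, Neb and Thada had 5 each. In all, 9 genes had at least 5 higher peaks, where 1000 random draws of peaks matched on level gave at most 1 such gene, with a median of 0. Neighbouring peaks are not independent, so the draws understate what chance gives. A further 125 higher peaks were over 50 kb from any protein-coding gene.

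Next to the chromosome 5 interval that was lower in cKO, a peak within Rbm47, an RNA-binding protein gene, went the other way (chromosome 5, 66034044 to 66034984). It stood at 5.43 ± 0.352 and 5.24 ± 0.512 CPM in WT control and WT Dex, and at 9.23 ± 0.958 and 9.65 ± 2.38 CPM in cKO control and cKO Dex (SD, n = 3). It was called for genotype in Dex-treated cells, at a log2 of 0.89 ± 0.17 (SE), and lost that call without cKO Dex replicate 2 at 0.72. The neighbouring tested peaks from 66031939, 66035576, 66038252 and 66046493, looked at after their values were seen, also had positive log2 values, from 0.47 to 1.03 in control and from 0.30 to 1.32 in Dex-treated cells, and were not called. Near Pmaip1, a peak from 66477874 on chromosome 18 rose with Dex in WT, at a log2 of 1.12 ± 0.26, while a peak from 66485414 stood at 5.85 ± 1.23 CPM in cKO Dex against 2.51 ± 0.483 CPM in WT Dex. The first of these lost its call without WT control replicate 1 (1.04), WT control replicate 3 (1.10), WT Dex replicate 1 (0.97) or WT Dex replicate 2 (1.14).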
